A study of Mus musculus with 43 samples.

How the data were processed

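Poly(A) RNA of mouse inguinal white adipose tissue was sequenced from 43 samples in 9 groups. Per the labels' protocols, the tissue was flash frozen and the libraries were made with a stranded mRNA kit. The deposited signal values are normalized counts per gene, in 5 tables that each hold the libraries of 1 comparison. Per the submitters' processing notes, the tools named are kallisto, which estimates transcript abundance, and DESeq2, which scales counts between libraries, with the mm10 build; versions, annotation and settings are not given in the sources used here. The 5 tables were normalized separately, so tests were made within a table and levels from different tables are not on 1 scale. The same 4 wild-type libraries at P28 and 22 C stand in both P28 tables. Gene totals of this kind do not show which exons of a gene were read.

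The deposited values are not whole numbers. Low values of a library were spaced by a common step, the worth of 1 read, from which depth was estimated at 3830000 to 6432000 reads per library in the P28 temperature table and 3503000 to 6432000 in the TrkA table. It was 4995000 to 15780000 in the P25 table, 16860000 to 30500000 in the table of Bcl6 genotypes in the cold, and 6275000 to 8696000 in the table of adult wild-type mice. Within a tolerance of 0.02, 71.3 to 74.4%, 69.6 to 74.8%, 68.9 to 74.1%, 34.9 to 51.5% and 28.2 to 49.9% of low values were whole multiples of the step in those tables, in the same order. Whole reads could therefore not be recovered for nearly all genes, and the depth estimates of the adult tables are rough.

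The design fixed before the data were examined assumed raw counts and a count model. Because the values are normalized, limma 3.58.1 in R 4.3.3 was used instead, with its mean-variance trend, on log2(value + 1). A gene was tested if it reached 10 in at least as many libraries as the smaller group holds. P-values were adjusted by the Benjamini-Hochberg method over the tested genes of a table, with a threshold of 0.05. Fold changes on this scale understate the change of genes with low values. Each table holds 22622 gene identifiers, of which 21 matched no symbol in the reference gene table. Gene coordinates are on mm10. Every column was matched to a group; columns of the P25 table carry a letter and number that match no sample title, and their libraries are named by them here.

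Named genes followed a rule fixed at the same point: the targeted genes and the gene whose promoter drives Cre, a panel of 12 genes, the 6 largest rises and 6 largest falls in which each library lay on its own side of the other group's mean, and up to 4 members with the smallest p in each described list. Some genes that the rule names, and a test that rests on the position of 1 of them, are not reported here. Members of 34 gene lists, fixed at the same point, were counted as risen or fallen, and each list was tested with limma's camera at a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and the rotation test fry were alternatives. The thermogenic list score is the mean log2 value of that list's measured members in a library, compared by a two-sided exact permutation test. With 4 libraries against 4 its smallest p is 0.0286. Effects in different tables were compared by a z test of the difference of log2 fold changes; a t reference was added after seeing the data.

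On simulated data with 200 changed genes, the test recovered 75.8%, 67.7%, 67.2%, 75.4% and 37.9% of genes changed 2-fold in the P28 temperature, TrkA, P25, adult Bcl6 and adult temperature tables. At 4-fold it recovered 96.9%, 87.3%, 93.7%, 90.6% and 87.1%, with 10, 4, 6, 5 and 3 false calls. With unchanged genes, the z test made 9 and 29 false calls in the comparisons of Bcl6 and of cooling effects, and the t reference 0 and 1. Simulated genes were drawn independently of each other. These counts of false calls therefore leave out structure shared between genes of the real libraries, such as sex or muscle content.

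The alternatives chosen with the design were other size factors, no filter, a stricter filter, a replicate block, each library left out in turn and other list tests. A covariate for Xist, a covariate for the skeletal muscle list, pseudocounts of 0.5 and 5, quantile normalization, library weights, a block by the P25 column code and splits balanced by Xist were chosen after seeing the data. No label says that samples of a group are separate animals, so p-values measure the spread between these samples. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.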

Results

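Gene expression was measured in inguinal white adipose tissue, the fat depot of the groin in which beige adipocytes, thermogenic fat cells, appear around weaning and again in the cold. The 43 libraries comprise wild-type mice at P28 kept at 22 C (n = 4) or 30 C (n = 4), and mice at P28 and 22 C carrying floxed TrkA with Th-cre (n = 4). Floxed Bcl6 mice without (n = 7) and with (n = 8) Prx1-cre were sampled at P25 and 22 C. The same Bcl6 genotypes at 9 weeks and 4 C (n = 4 each) and wild-type mice at 9 weeks and 22 C or 4 C (n = 4 each) complete the series. Th-cre acts in cells that make tyrosine hydroxylase. Bcl6 is a transcriptional repressor, and Prx1-cre acts in limb and other mesenchyme. Estimated depth ran from 3503000 reads in the shallowest library, at P28, to 30500000 in the deepest, at 9 weeks. By the series title, the comparisons ask whether development of beige fat near weaning and its recruitment by cold use different pathways.

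The first comparison asks what housing at 30 C changes at P28 in wild-type mice. Ucp1 (gene ID 22227, mm10 chromosome 8, 83290348 to 83298456), the proton carrier that makes brown and beige fat thermogenic, fell from 1758 ± 570 normalized counts at 22 C (SD, n = 4) to 109 ± 52 at 30 C (SD, n = 4), a log2 fold change of -4.06 ± 0.37 (SE; limma adjusted p = 0.0017). Of 26 measured members of the thermogenic list, 11 fell and 15 did not pass; adjusted over the list alone, 14 fell and 1 rose. Otop1, a proton channel, fell from 220 ± 61.2 to 43.1 ± 17.2, glycerol kinase Gk from 199 ± 18.4 to 72.9 ± 23.9, and the cytochrome oxidase subunit Cox7a1 from 188 ± 19 to 68.6 ± 25.1. The panel gene Cidea did not pass, at -0.86 ± 0.23 (adjusted p = 0.0754). The thermogenic list score was lower at 30 C by a difference of -0.68 (exact permutation p = 0.0286, n = 4 and 4, the smallest possible), and 0.0571 with any 1 of the 4 libraries at 30 C left out.

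Genes of mitochondrial fuel use also fell at 30 C. In the list of nuclear-encoded oxidative phosphorylation genes 29 of 37 members fell, 34 adjusted over the list alone, among them Cycs, cytochrome c, at -0.85 ± 0.08, and Etfdh at -0.84 ± 0.08. In fatty acid oxidation 15 of 23 fell, 18 adjusted over the list alone, including Acadm at -0.92 ± 0.08 and Cpt2 at -0.76 ± 0.07. In the citric acid cycle 15 of 17 fell, 16 adjusted over the list alone, including Idh3a at -0.96 ± 0.10. Of 18 cholesterol synthesis genes 4 fell, 6 adjusted over the list alone, and of 17 fatty acid synthesis genes 2 fell, 13 adjusted over the list alone. Those 2 were Scd1, which makes monounsaturated fatty acids, at -1.40 ± 0.21, and Acacb at -1.07 ± 0.23. Camera's adjusted p was 1.3e-30 for oxidative phosphorylation and 4.78e-07 for the thermogenic list. With an estimated correlation these became adjusted p = 0.284 and adjusted p = 0.438, and neither call held. By fry both lists passed, at adjusted p = 0.00411 and adjusted p = 0.0492.

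Other genes rose at 30 C. Of 14 genes of the adrenergic and cAMP response list 5 rose, 7 adjusted over the list alone with 2 that fell, including Rgs2, a regulator of G protein signalling, from 160 ± 23.4 to 491 ± 97.5, and Irf4 at 1.24 ± 0.16 (camera adjusted p = 0.000404; adjusted p = 0.335 with an estimated correlation). In the macrophage list 4 of 24 rose, also adjusted over the list alone, with Lyz2 at 0.46 ± 0.10 (camera adjusted p = 4.06e-06; adjusted p = 0.438 with an estimated correlation). Nnat rose at 1.16 ± 0.17, and Cish, induced by cytokine signalling through Stat5, fell at -1.84 ± 0.25. The other largest falls were Serpina3k, Hephl1, Ncan and Gys2, and the other largest rises R3hcc1, Olfr1033, Txlnb, Cyp2f2 and Slc10a6. Of 16 glycolysis genes 4 fell, 10 down and 1 up adjusted over the list alone. The Schwann cell, smooth muscle, T and NK cell, and B cell lists had medians of 0.385, 0.297, 0.185 and 0.133. Camera's adjusted p was 0.00314, 0.0222, 0.00163 and 0.0208, and with an estimated correlation adjusted p = 0.533, 0.533, 0.645 and 0.76. Of their members 1 fell in the Schwann cell list and 1 rose in each of the smooth muscle and T and NK cell lists. Skeletal muscle transcripts, with a list median of 2.45 over 12 genes, were high in 3 libraries at 30 C, with list scores of 8.13, 8.15 and 10.01 against 4.91 to 5.71 at 22 C and 4.19 in replicate 3 at 30 C.

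In all, 547 of 12283 tested genes changed between the temperatures, 158 up and 389 down at 30 C, of which 63 by a log2 fold change of at least 1 (limma adjusted p under 0.05). Leaving out replicate 1, 2 or 4 at 22 C gave 305, 200 and 176 genes, and leaving out replicates 1 to 4 at 30 C gave 280, 289, 317 and 315. Of 61 named genes past the threshold, 30, Ucp1 among them, passed in each of these fits, and with the skeletal muscle score as a covariate, which itself differs between the temperatures, 79 genes passed. The mix of sexes by Xist differed, with Xist high in 2 of 4 libraries at 22 C and 3 of 4 at 30 C. With an Xist indicator as a covariate, chosen after seeing the data, 531 genes passed, 451 of them among the 547.

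**Figure D1:**
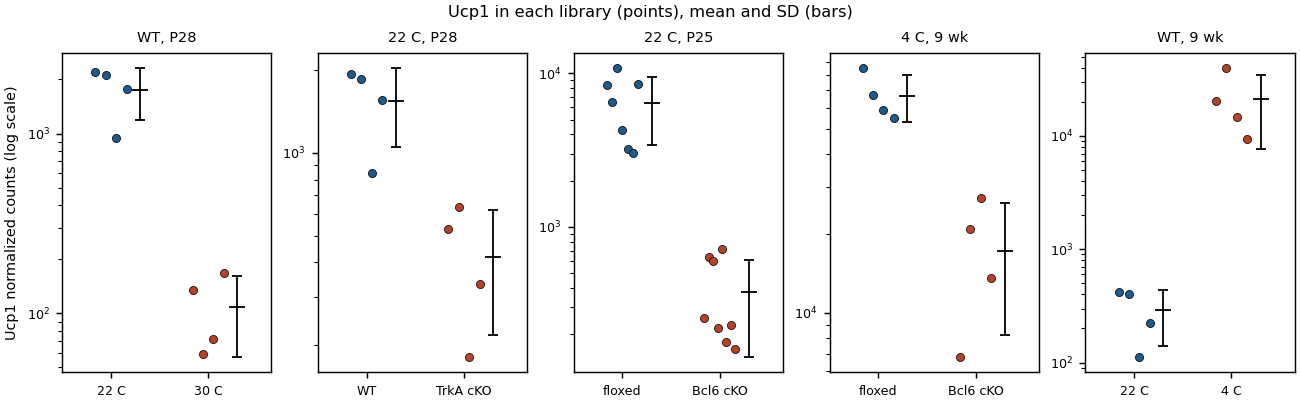
Ucp1 in normalized counts (log scale) in each library, 1 panel per comparison, with points for libraries and bars for mean and SD. Panels come from separately normalized tables. Ucp1 lay between 59.3 and 168 in the 4 libraries at 30 C and between 950 and 2194 in the 4 at 22 C.

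The second comparison asks what differs at P28 and 22 C between wild-type mice and mice that carry floxed TrkA with Th-cre. By their labels the controls are wild-type mice of a named strain, not floxed TrkA mice without Cre. The contrast therefore holds the floxed allele, Th-cre and any difference of strain or litter together. Ucp1 fell from 1545 ± 497 in wild-type to 419 ± 202 in TrkA Th-cre libraries (SD, n = 4 each), a log2 fold change of -1.96 ± 0.38 (limma adjusted p = 0.0284). Th, whose promoter drives the Cre, was listed at 0 in each wild-type library, so it does not check the genotype labels. Of 26 thermogenic genes 4 fell, 10 adjusted over the list alone: Ucp1, Gk at -1.34 ± 0.16, Cox7a1 at -1.23 ± 0.21 and Acsf2 at -0.57 ± 0.11. Cidea was at -0.32 ± 0.23 and did not pass. The list's median was -0.50 (camera adjusted p = 5.53e-05; adjusted p = 0.559 with an estimated correlation and adjusted p = 0.165 by fry), or -0.14 with the muscle score as a covariate (camera adjusted p = 0.0211), and its score differed by -0.45 (exact permutation p = 0.0571, n = 4 and 4), which missed the threshold.

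Cholesterol synthesis genes fell in 5 of 17 cases, 15 adjusted over the list alone, among them Cyp51 at -1.15 ± 0.20 (camera adjusted p = 1.83e-12; adjusted p = 0.493 with an estimated correlation). Of 17 Schwann cell genes 2 fell, Cdh19 at -1.04 ± 0.22 and Pllp at -1.25 ± 0.28, and 15 fell and 1 rose adjusted over the list alone (camera adjusted p = 2.25e-07; adjusted p = 0.493 with an estimated correlation). Of 22 macrophage genes 8 rose, 12 adjusted over the list alone, among them Lyz2 from 1844 ± 152 to 2997 ± 242, Mrc1 at 0.78 ± 0.12 and Csf1r, the receptor for macrophage growth factor, at 0.77 ± 0.13 (camera adjusted p = 8.16e-08; adjusted p = 0.493 with an estimated correlation). Of 13 immediate early genes 3 fell, 6 adjusted over the list alone. Of 13 skeletal muscle genes 3 rose, 12 adjusted over the list alone, Myh2, Mybpc2 and Ttn. The muscle score was 5.83 to 8.28 in TrkA Th-cre and 4.51 to 5.21 in wild-type libraries.

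The largest rises were Hal, the enzyme that breaks down histidine, from 0.699 ± 0.479 to 272 ± 163, followed by Ifi202b, Gbp2b, Mettl7a3, Mettl7a2 and Trim34b. Ifi202b was listed at 0 in each wild-type library. The netrin receptor Unc5a fell from 212 ± 65.8 to 4.43 ± 5.12 and Trim30b from 28.4 ± 7.97 to 1.33 ± 2.66. The gut genes Hnf4a, Mptx1 and Gsdmc4 fell too, as did Fosb, but their wild-type libraries stood apart from each other: Hnf4a was at 131, 630 and 216 in replicates 2, 3 and 4 against 12.7 in replicate 1, and at most 8.07 in TrkA Th-cre libraries. Epithelial genes varied in the same way. The mammary epithelium list had a median of -1.99 over 12 genes, none of which passed alone (limma, 2280 genes at an unadjusted p under 0.05). As a set it had camera adjusted p = 0.0215, or adjusted p = 0.835 with an estimated correlation. Xist was high in 2 wild-type libraries and 1 TrkA Th-cre library. With an Xist indicator as a covariate, chosen after seeing the data, the median was -0.91 (camera adjusted p = 0.203), and the call did not hold. Krt8, a keratin, was at 22.9, 773, 3893 and 1857 in wild-type replicates 1 to 4 and between 8.65 and 529 in TrkA Th-cre libraries.

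Of 11899 genes 317 changed, 160 up and 157 down, 135 of them by a log2 fold change of at least 1 (limma adjusted p under 0.05). Leaving out wild-type replicate 2 or 4 gave 101 and 93 genes, leaving out TrkA Th-cre replicates 1, 2 and 3 gave 95, 115 and 119 and replicate 4 gave 870, and with the muscle score as a covariate, which differs between the genotypes, 20 passed. Of 47 named genes past the threshold 11, with Hal and Gk, passed without any 1 library, while Ucp1 had adjusted p = 0.0872 and 0.0859 without wild-type replicates 2 and 4, 0.063 without TrkA Th-cre replicate 1 and 0.339 with the muscle covariate.

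The 2 P28 comparisons use the same 22 C wild-type libraries. Genes that rose in both numbered 30 and genes that fell in both 38, with 1 in opposite directions, against 0 from unchanged simulated groups and 1.89 and 5.16 from independent lists. Unchanged groups yield almost no calls to share, by construction, and independent lists leave out the shared controls. Neither is therefore a baseline for these counts. With the controls split, 2 to each comparison, 0.5 rose and 1.5 fell in both on average, but the smaller groups lower this count by construction. Across 11827 genes, which are not independent replicates, the log2 fold changes correlated at r = 0.352, against 0.469 for simulated unchanged groups sharing the controls and 0.13 with the controls split. The covariance was 0.0605 against a simulated mean of 0.0442. Both lay inside the range of the 100 simulated draws, -0.216 to 0.861 for r and -0.0138 to 0.188 for the covariance, so across all genes no relation beyond the shared controls was shown.

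The third comparison asks what differs at P25 between floxed Bcl6 mice labelled with and without Prx1-cre. The Bcl6 gene total (gene ID 12053, mm10 chromosome 16, 23965050 to 23988866) was higher in the libraries labelled Prx1-cre, at 2714 ± 584 (SD, n = 8), than in those labelled floxed, at 825 ± 340 (SD, n = 7), a log2 fold change of 1.78 ± 0.23 (limma adjusted p = 0.000235). The total did not fall with the knockout label, but gene totals do not show whether the deleted exons are missing. A higher total thus neither bears out nor contradicts the label. Each direction for Bcl6 genotypes is therefore drawn between libraries as labelled. Prrx1, whose promoter drives the Cre, was at 746 ± 470 and 758 ± 324.

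**Figure D2:**
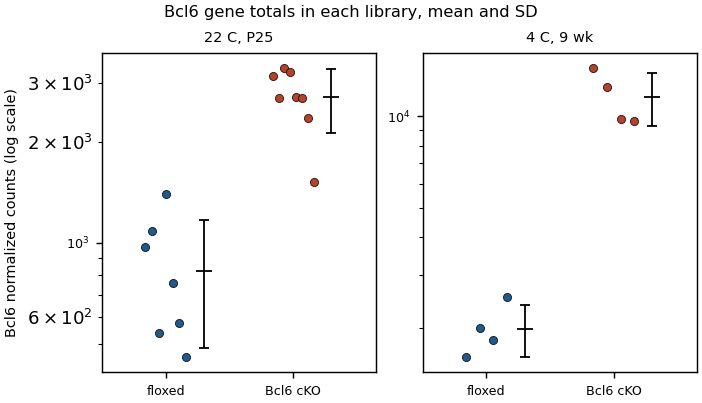
Bcl6 gene totals in normalized counts (log scale) in each library at P25 and at 9 weeks, with points for libraries and bars for mean and SD. At both ages each library labelled Prx1-cre lies above each library labelled floxed, 1517 to 3329 against 454 to 1395 at P25 and 9624 to 14490 against 1607 to 2529 at 9 weeks, and the tables were normalized separately.

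In the libraries labelled Prx1-cre at P25, Ucp1 fell from 6405 ± 3016 to 375 ± 234, a log2 fold change of -4.18 ± 0.38 (n = 7 and 8; limma adjusted p = 6.48e-06). Of 27 thermogenic genes 14 fell and 2 rose, 17 and 2 adjusted over the list alone. Cidea, a lipid droplet protein of thermogenic fat, fell from 4342 ± 1326 to 1477 ± 474, Otop1 from 518 ± 138 to 161 ± 55.4, and the fatty acid elongase Elovl3 from 125 ± 80.7 to 7.87 ± 4.68. The 2 that rose were the coactivator Ppargc1a, at 0.56 ± 0.14, and the nucleoside transporter Slc29a1, at 1.27 ± 0.13. The list score differed by -1.01 (exact permutation p = 0.000155, the smallest that 7 against 8 can give), with no overlap between the groups. Of 23 fatty acid oxidation genes 16 fell, 20 adjusted over the list alone, with Acot11 at -2.32 ± 0.36, Crat at -0.97 ± 0.12 and Hadhb at -0.81 ± 0.13. Camera's adjusted p was 1.79e-15 for the thermogenic list and 6.29e-23 for fatty acid oxidation, and each had adjusted p = 0.0776 with an estimated correlation.

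Mest, an imprinted gene that marks expanding fat, rose in the libraries labelled Prx1-cre from 549 ± 251 to 13670 ± 5785, a log2 fold change of 4.65 ± 0.34 (limma adjusted p = 5.7e-07). Gpr179, Tmem215, the glucagon receptor Gcgr and Usp29 were among the other largest rises, at 5.03, 3.95, 3.81 and 3.55. Socs2, a feedback inhibitor of growth hormone signalling, rose from 226 ± 60.1 to 1618 ± 351. Of 27 extracellular matrix genes 8 rose, 11 adjusted over the list alone, with Col12a1 at 1.75 ± 0.25 and Thbs1 at 1.22 ± 0.16 (camera adjusted p = 1.29e-10; adjusted p = 0.862 with an estimated correlation). Lists of other cell types moved too, with a median of 0.72 over 24 macrophage genes, of which 21 were positive, -1.51 over 16 skeletal muscle genes and -0.29 over 18 Schwann cell genes (camera adjusted p = 0.00108, 0.0266 and 0.00788; adjusted p = 0.862 for each with an estimated correlation). Of these genes 1, in the Schwann cell list, passed alone. The other largest falls were Acat3, the fatty acid transporter Slc27a2, and Acsm3. Adipoq, the adiponectin gene, was at 0.01 ± 0.13 and did not pass, nor did Fasn at -0.11 ± 0.35.

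Of 12738 genes 450 changed, 199 up and 251 down, 122 of them by a log2 fold change of at least 1 (limma adjusted p under 0.05). Leaving out the floxed library M3 gave 288. Of 44 named genes past the threshold 38 passed without any 1 library, among them Bcl6, Ucp1, Cidea, Elovl3, Mest and Socs2.

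The fourth comparison sets the same genotypes side by side at 9 weeks and 4 C. The Bcl6 gene total was again higher in the libraries labelled Prx1-cre, 11610 ± 2339 against 1995 ± 392 (SD, n = 4 each, log2 fold change 2.54 ± 0.17, limma adjusted p = 0.000209), so that it again did not fall with the label. In these libraries Ucp1 fell from 66630 ± 13560 to 17140 ± 8930, a log2 fold change of -2.12 ± 0.39 (adjusted p = 0.00998). Of 27 thermogenic genes 18 fell and 2 rose, 20 and 2 adjusted over the list alone, including Elovl3 at -3.59 ± 0.46, Slc27a2 at -3.33 ± 0.45 and Cidea at -2.13 ± 0.34 down and Slc29a1 at 1.38 ± 0.16 up. The list score differed by -1.15 (exact permutation p = 0.0286, n = 4 and 4, the smallest possible). Of 23 fatty acid oxidation genes 17 fell, 20 adjusted over the list alone, with Ehhadh at -1.82 ± 0.22, and of 37 oxidative phosphorylation genes 7 fell, 7 adjusted over the list alone. Camera's adjusted p was 8.86e-09 for the thermogenic list, 3.27e-12 for fatty acid oxidation and 3.07e-07 for oxidative phosphorylation. With an estimated correlation the p-values were adjusted p = 0.609, adjusted p = 0.609 and adjusted p = 0.744.

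Extracellular matrix genes rose in the libraries labelled Prx1-cre at 9 weeks, 19 of 27, and 22 adjusted over the list alone, with tenascin C (Tnc) from 182 ± 31.6 to 1172 ± 352 and Col6a1 at 1.41 ± 0.14. This list kept its call with an estimated correlation (adjusted p = 0.00333; camera adjusted p = 1.35e-14). Of 24 macrophage genes 11 rose, 13 up and 1 down adjusted over the list alone, with Cd68 at 1.12 ± 0.11 and Trem2 at 1.72 ± 0.25 (camera adjusted p = 2.68e-06; adjusted p = 0.609 with an estimated correlation). Of 19 endothelial genes 3 rose, Aqp1, Plvap and Vwf, 5 adjusted over the list alone (camera adjusted p = 0.000199; adjusted p = 0.744 with an estimated correlation). White adipocyte genes rose in 5 of 21 cases and fell in 1, 6 and 1 adjusted over the list alone, led by Mest, from 251 ± 190 to 27480 ± 12480, Nnat at 2.02 ± 0.22, and Npr3 at 1.74 ± 0.31 (camera adjusted p = 0.0115; adjusted p = 0.744 with an estimated correlation). Socs2 rose at 3.67 ± 0.27. Other large rises included Gpr179, Akr1cl, Rgs16 and Wnt8b, and the largest falls were Brms1, Cyp2b10, Acat3, Mup13, Elovl3 and Fam131c. The floxed library 3 had a skeletal muscle score of 13.31, against 4.0 to 8.72 in the other libraries.

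Of 13496 genes 1953 changed, 1216 up and 737 down, 535 of them by a log2 fold change of at least 1 (limma adjusted p under 0.05). Leaving out floxed replicates 1, 2 and 3 gave 1055, 1095 and 3548 genes, and leaving out replicates 1 and 2 labelled Prx1-cre gave 1098 and 1251. Of 88 named genes past the threshold 62 passed without any 1 library, and with the muscle score as a covariate 3041 genes passed.

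The genotype effects at the 2 ages, which also differ in temperature and in the mix of sexes by Xist, were then compared. At 9 weeks Xist was high in 4 of 4 libraries of each group. At P25 it was high in 3 of 7 floxed libraries and 4 of 8 labelled Prx1-cre. Of 315 genes called at both, 313 had the same sign, 152 up and 161 down in the libraries labelled Prx1-cre, where independent lists give 18.6 and 14.2. Across 12487 genes, not independent replicates, the effects correlated at r = 0.664. The effects differed for 166 genes by the z test, 38 with a t reference. By the z test Ucp1 fell further at P25 than at 9 weeks (difference -2.06 ± 0.55, z test adjusted p = 0.0223). Dlk1, a preadipocyte gene, rose at P25 by 2.81 ± 0.29 and was at -0.75 ± 0.40 at 9 weeks (z test adjusted p = 2.62e-09). Whether either gene differs with the t reference, which called fewer genes, is not given here. The difference for the thermogenic list did not pass (median 0.41; camera adjusted p = 0.0773), while the extracellular matrix list rose further at 9 weeks (median difference -0.51; camera adjusted p = 1.61e-05). Without floxed library M4 of P25 the z test gave 250 genes, and without floxed replicates 1 or 3 or replicates 1 or 2 labelled Prx1-cre at 9 weeks it gave 90, 791, 94 and 88.

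The fifth comparison asks what 4 C changes in wild-type mice at 9 weeks. Ucp1 rose from 289 ± 150 at 22 C to 21150 ± 13420 at 4 C (SD, n = 4 each), a log2 fold change of 6.17 ± 0.53 (limma adjusted p = 0.00248). Of 27 thermogenic genes 9 rose and 1, Ntrk3, fell; adjusted over the list alone 14 rose and 2 fell. The fatty acid binding protein Fabp3 rose from 32.2 ± 11.4 to 2302 ± 1577, Elovl3 from 26.1 ± 7.6 to 1343 ± 733 and Gk from 117 ± 40.5 to 2396 ± 1505. Cidea was at 1.76 ± 0.61 and did not pass (adjusted p = 0.126). The list score differed by 1.48 (exact permutation p = 0.0286, n = 4 and 4, the smallest possible), and p was 0.0571 without replicate 3 or 4 at 22 C. Camera's adjusted p for the list was 4.51e-07, with adjusted p = 0.673 with an estimated correlation and adjusted p = 0.0885 by fry.

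Of 23 fatty acid oxidation genes 4 rose at 4 C, 12 adjusted over the list alone, led by Acot11 at 2.05 ± 0.37 (camera adjusted p = 1.7e-07; adjusted p = 0.673 with an estimated correlation). Cyp2b10 had the largest rise, from 1.44 ± 0.97 to 1524 ± 981, followed below Ucp1, Fabp3 and Elovl3 by Sgk2 and Ergic1. Agt, the angiotensin precursor, rose at 3.13 ± 0.31. Of 17 Schwann cell genes 5 fell, 9 adjusted over the list alone, among them the myelin genes Mbp, from 1224 ± 116 to 614 ± 62.8, and Prx at -0.98 ± 0.09. The list had camera adjusted p = 4.51e-07, adjusted p = 0.182 with an estimated correlation and adjusted p = 0.000476 by fry. In the extracellular matrix list 4 of 27 fell and 1, Lox, rose, 7 and 1 adjusted over the list alone, and of 18 endothelial genes 3 fell, 8 adjusted over the list alone (camera adjusted p = 0.00126 and 0.00016). With an estimated correlation these had adjusted p = 0.689 and adjusted p = 0.6. The largest falls were Baiap2l2, Nnat, Ntsr2, Crtac1, Mest and Ntrk3. Clock genes went both ways, with 2 rising and 4 falling of 17, and 4 and 5 adjusted over the list alone, with Arntl at 2.59 ± 0.43 and Dbp at -2.23 ± 0.28. Muscle scores varied within both groups, from 2.04 to 10.37 at 22 C and 1.57 to 9.68 at 4 C.

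Of 12118 genes 542 changed, 246 up and 296 down at 4 C, 259 of them by a log2 fold change of at least 1 (limma adjusted p under 0.05). Leaving out replicates 1 to 4 at 22 C gave 72, 96, 356 and 98 genes and replicates 1 to 4 at 4 C gave 36, 155, 192 and 170, and of 53 named genes past the threshold 16, with Ucp1, Elovl3, Fabp3, Gk and Cyp2b10, passed without any 1 library. Without the filter 356 passed, with the muscle score as a covariate 1745 and with an Xist indicator 2226, both added after seeing the data; each group held 2 libraries with high Xist.

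**Figure D3:**
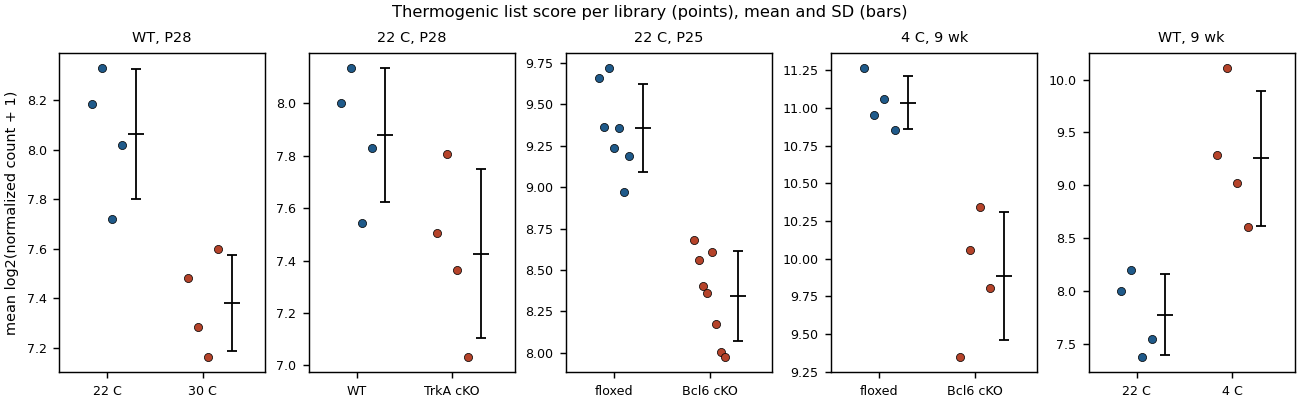
Thermogenic list score, the mean log2(normalized count + 1) of the list's measured genes, in each library, 1 panel per comparison, with points for libraries and bars for mean and SD. In the adult wild-type panel the 4 libraries at 4 C lie between 8.61 and 10.11 and the 4 at 22 C between 7.38 and 8.20; scales of different panels are not comparable.

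Cooling of juveniles, 22 C against 30 C at P28, was compared with cooling of adults, 4 C against 22 C at 9 weeks, which differ in age and in temperature step. Of 39 genes called in both 37 had the same sign, 28 up and 9 down on cooling, where independent lists give 7.77 and 3.95, and across 11618 genes, not independent replicates, r was 0.115. The effects differed for 1051 genes by the z test and 387 with a t reference, with 666 by the z test without replicate 1 at 4 C. Single genes are given here by the z test, and whether they differ with the t reference is not given. Ucp1 rose less in juveniles (difference -2.11 ± 0.65, z test adjusted p = 0.0194). Ppargc1a was at -0.22 ± 0.15 in juveniles and 1.41 ± 0.40 in adults (z test adjusted p = 0.00348). It passed at neither age alone (limma adjusted p = 0.484 and 0.0773). In adults at 4 C Ppargc1a was at 1032 in replicate 2 and at 278.6 to 384.5 in the other libraries. Fabp3 was at 0.12 ± 0.25 in juveniles and rose by 5.92 ± 0.46 in adults (adjusted p = 3.67e-24). Median effects of the fatty acid synthesis list were 0.80 in juveniles and -0.24 in adults (camera adjusted p = 1.09e-05), and of the thermogenic list 0.45 and 0.99 (camera adjusted p = 0.00268). Both were tested only at the preset correlation, with neither an estimated correlation nor fry.

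Genes that changed in the adult cold by a log2 fold change of at least 1, 110 up and 149 down, were followed in the other tables. Of those that rose in the cold, 21 fell and 1 rose of 96 measured at 30 C, and 8 fell and 1 rose of 94 in TrkA Th-cre libraries. In libraries labelled Prx1-cre 18 fell and 4 rose of 103 at P25, and 54 fell and 8 rose of 109 at 9 weeks, with median log2 fold changes of -0.21, -0.21, -0.17 and -0.56 in that order. Of those that fell in the cold, 47 rose and 4 fell of 149 in the 9-week libraries labelled Prx1-cre (median 0.36). Camera's adjusted p-values for these 5 sets were 9.72e-08, 4.76e-05, 1.17e-05, 2.25e-11 and 9.12e-09. With an estimated correlation they were adjusted p = 0.161, 0.244, 0.148, 0.173 and 0.148, and no call held. In P25 libraries labelled Prx1-cre 12 rose and 2 fell of 149 cold-fallen genes (median 0.15; camera adjusted p = 0.0134; adjusted p = 0.396 with an estimated correlation). The cold-fallen genes did not pass as a set at 30 C (median 0.06; camera adjusted p = 0.102) or in TrkA Th-cre libraries, where 5 rose and 5 fell of 145 (median -0.09; camera adjusted p = 0.136).

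**Figure D4:**
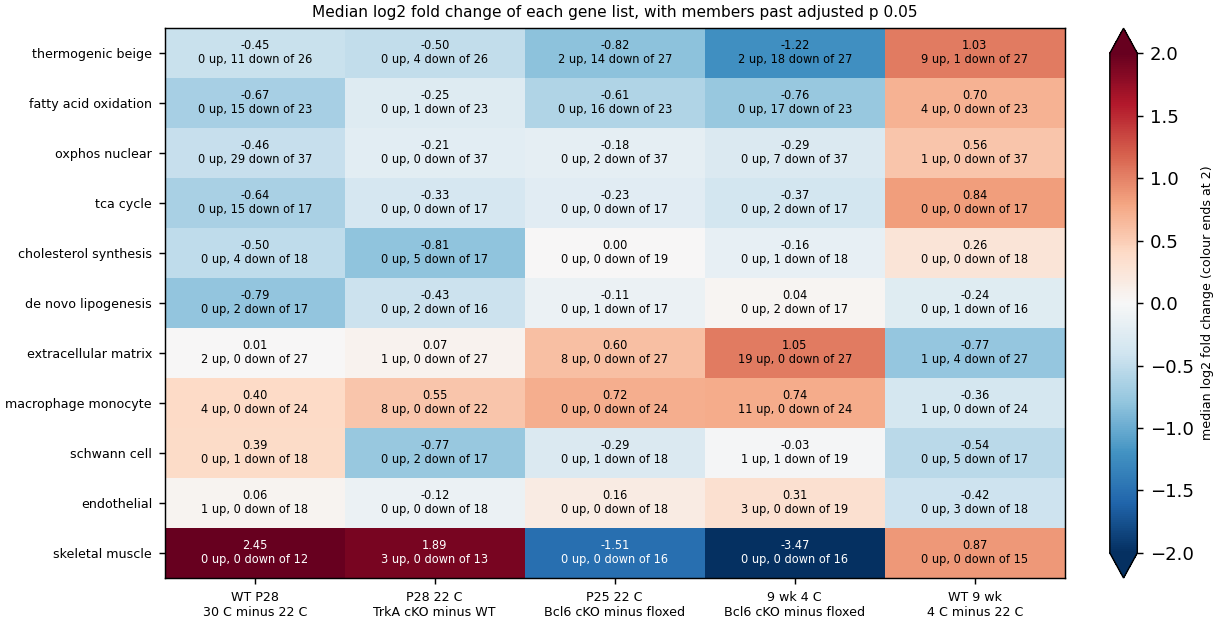
Median log2 fold change of 11 gene lists in the 5 comparisons, by colour and number, with the count of members past adjusted p 0.05 in each direction. The thermogenic list's medians are -0.45, -0.50, -0.82, -1.22 and 1.03; genotype columns for Bcl6 follow the libraries as labelled.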

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

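For Bcl6, the tests of single mislabelled libraries, of scaling and of exchanged group labels were chosen after the result was seen, as were the test of sex in the TrkA comparison and both clock gene tests.

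The Bcl6 gene total was higher in libraries labelled Prx1-cre at both ages. Of 23 libraries 0 lay nearer the other group's mean, which argues against single wrong labels. At P25 0.549% of genes and at 9 weeks 0.482% rose as much as Bcl6 less 2 SE. The values were already scaled between libraries, with a median log2 fold change over all tested genes of 0.004 and -0.016. A low share was therefore set beforehand, and it does not test scaling. With the skeletal muscle covariate Bcl6 stayed at 1.89 at P25 and 2.52 at 9 weeks, which argues against muscle tissue. Labels exchanged between whole groups and a genotype effect on the remaining transcript cannot be told apart, since gene totals hold no value for the deleted exons (log2 fold change 2.54 at 9 weeks). The genotype the design names stays among the open explanations.

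In the TrkA comparison 3 genes, Hal, BC018473 and Ifi202b, were under 5 in each library of 1 genotype and over 50 in each of the other, against 0 between temperatures with the same wild-type libraries (BC018473 was named after its values were seen). Xist was high in 2 of 4 wild-type and 1 of 4 TrkA Th-cre libraries, so each genotype held both classes. Genes that separate every library by genotype thus argue against sex, for these 3 genes. Over all calls, 239 of 317 were shared with the fit that holds the Xist indicator. A different strain background of the knockout may contribute, but called neighbours of like direction numbered 41 against a mean of 35.7 and a 95th percentile of 45 in random draws. The same count passed that percentile in the P25 (98 against 78), adult Bcl6 (736 against 723) and adult wild-type tables (118 against 105), and both groups of the last are labelled wild type, so it does not single out strain. The controls are wild-type mice rather than floxed TrkA mice without Cre, so strain, litter and an effect of genotype cannot be told apart.

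In adults at 4 C, 12 of 14 clock genes with a known phase, Arntl left out, moved in the direction that Arntl sets. The mean log2 value of clock genes in phase with Arntl less that of genes against it, which no scale factor changes, was higher at 4 C by 2.00 without overlap (exact permutation p = 0.0286, n = 4 and 4, the smallest possible), which argues against scaling. This score holds the genes whose opposite movement prompted it, Arntl and Dbp among them, so its p is no separate support for the pattern. Sacrifice at different hours could give this pattern, and so could the cold itself. The labels give no hour, so these cannot be told apart.

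Of 140 groups of values, 5 held a library far from the others, where chance gives about 7. These were a muscle score of 9.44 in floxed library M2 at P25, here over all members in the table, and Ppargc1a at 300.2 in floxed library M1 at P25. Floxed replicate 3 at 9 weeks had Adipoq at 102700 and Prrx1 at 1828. Ppargc1a was at 1032 in wild-type replicate 2 at 4 C.

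The Bcl6 genotype effect differed between P25 and 9 weeks by the z test for 11 named genes, given as the log2 difference P25 minus 9 weeks between libraries as labelled. It was higher at P25 for Dlk1 (3.56), Ergic1 (2.39), St3gal5 (1.80), Gmpr (1.65) and Cux1 (0.72), and lower for Ucp1 (-2.06), Gpx3 (-1.70), Lypd1 (-2.21), Rgs16 (-1.89), Tnc (-1.79) and Vnn1 (-1.99).

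The cooling effect differed by the z test between P28 and 9 weeks for 12 named genes, given as P28 minus 9 weeks. It was higher at P28 for Aplnr (2.44), Fam20c (2.11), Unc119 (1.58), Ednra (1.49) and Slc28a2 (1.29), and lower for Ucp1 (-2.11), Ppargc1a (-1.63), Fabp3 (-5.80), Agt (-3.45), Rgs2 (-3.04), Ttpa (-2.46) and Slc3a2 (-1.67).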

How the results depend on the processing

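Covariates for Xist and for skeletal muscle, pseudocounts of 0.5 and 5, quantile normalization, library weights and the t reference were chosen after seeing the data. The planned edgeR and DESeq2 fits were not run, since whole reads were not recovered. Size factors recomputed by the median of ratios were the same for each library of a table (1.002 to 1.004), so that alternative moved nothing, and the stricter filter removed no tested gene in either P28 table; neither says anything about stability.

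Counts of changed genes in the P28 temperature, TrkA, P25, adult Bcl6 and adult temperature tables were 63, 135, 122, 535 and 259 with a log2 fold change of at least 1, by construction. With the muscle covariate they were 79, 20, 343, 3041 and 1745, and with library weights 905, 957, 577, 4777 and 1872. The adult temperature count was 356 without a filter, where more genes are tested, and 2226 with the Xist covariate. The genes with differing Bcl6 and cooling effects numbered 38 and 387 with the t reference, and the cooling count was 1753 with the Xist covariate. Except for the threshold and the filter, the cause was not tested.

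With an estimated correlation the thermogenic list lost its call in each comparison, at unchanged medians of -0.45, -0.50, -0.82, -1.22 and 1.03, as did the adult cold genes, at -0.21, -0.21, -0.17 and -0.56 for those that rose and 0.15 and 0.36 for those that fell in P25 and 9-week Bcl6 libraries. By fry the thermogenic list lost it for TrkA (adjusted p = 0.165) and for adult temperature (adjusted p = 0.0885) and passed in the other tables. The controls of the P28 overlap, split, left 2 shared calls, by construction, with 2 controls in each fit. With the muscle covariate the thermogenic list's median in the TrkA table was -0.14 (camera adjusted p = 0.0211). The muscle list reversed at 30 C to -0.38 with the muscle covariate, by construction.

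Replicate numbers did not pair the samples: same-number correlations were -0.66, -0.02, -0.30 and -0.49 in the P28 temperature table, 0.12, 0.15, 0.21 and -0.14 for TrkA, -0.28, -0.05, -0.35 and 0.16 for adult Bcl6 and -0.26, 0.77, 0.50 and 0.51 for adult temperature, and in no table did each sample correlate best with its own number. With numbers as a block, counts were 236, 257, 1171 and 1666, and 2026 genes differed in cooling effect. For adult temperature, libraries of the same number had the same Xist class, so there the block also holds sex. The letters and numbers of the P25 columns match no sample title, but Xist was high in each F column and low in each M column. A block by these codes therefore also holds sex. Used as a block, chosen after seeing the data, they gave 731 genes; of 7 codes in both groups 5 had a same-code correlation over 0.1 (range -0.22 to 0.62) and 4 matched best with their own, so they did not pair the samples either.

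Leaving out 1 library gave 176 to 714, 93 to 870, 288 to 666, 1055 to 3548 and 36 to 356 changed genes in table order, and thermogenic score differences of -0.80 to -0.60, -0.58 to -0.32, -1.08 to -0.95, -1.30 to -0.97 and 1.19 to 1.69. Genes that differ ran from 88 to 791 for the Bcl6 effect and 666 to 1262 for cooling. Counting each pair of a named gene and a library left out, 690 lost a call, 105 gained it and 5982 kept their side of the threshold. Counting each pair of a result and another setting, named genes lost a call in 219, gained it in 345 and kept their side in 6485. Lists lost a call in 131, gained it in 12, reversed in 1 and kept their side of the threshold in 729. In 157 cases a value that passed neither way changed sign. On simulated data 27.3%, 18.8%, 47.8%, 29.2% and 10.4% of 1.5-fold changes were recovered in table order, so small changes were missed in each table; the part that depth plays was not tested.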

Other observations

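The list of imprinted genes and its tests were chosen after the largest rises were seen, with the predictions for the remaining members written before their result, and the splits balanced by Xist, the regroupings that keep neither real split and the test without Peg3 and Zim1 were added after the other splits were seen.

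In the adult cold the cell cycle list had a median log2 fold change of -0.90 over 21 genes, of which none passed alone (limma, 2886 of 12118 genes at an unadjusted p under 0.05; camera adjusted p = 0.000314; adjusted p = 0.673 with an estimated correlation). Of 16 interferon response genes 2 fell, among them Ifit3 at -1.62 ± 0.30, and 6 adjusted over the list alone (camera adjusted p = 1.3e-05; adjusted p = 0.673 with an estimated correlation). The T and NK cell list had a median of -1.58 over 13 genes, of which none passed alone (camera adjusted p = 0.000433; adjusted p = 0.673 with an estimated correlation). The B cell and lymph node list had a median of -3.15 over 6 genes, of which 5 fell and 1, Cxcl13, rose adjusted over the list alone, while the list itself did not pass (camera adjusted p = 0.0992). Cd79a, a B cell gene, was at 252 and 392 in replicates 1 and 3 at 22 C, at 8.76 and 21.3 in replicates 2 and 4, and between 1.13 and 31.6 at 4 C. In creatine and calcium cycling, Ckb and Atp2a2 rose at 1.34 ± 0.29 and 0.72 ± 0.15 while Gatm and Gamt, which make creatine, fell at -1.03 ± 0.14 and -1.89 ± 0.38. In the libraries labelled Prx1-cre Ifi27l2a fell at both ages, at -1.48 ± 0.17 at P25 and -1.42 ± 0.25 at 9 weeks.

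Several of the largest rises in libraries labelled Prx1-cre are imprinted genes. A hypothesis is that imprinted genes rise as a set. Leaving out Mest, Usp29, Cdkn1c, Dlk1 and Nnat, which were seen first, 25 remaining members had a median log2 fold change of 0.16 at P25, with 4 rising (camera p = 0.00309, 0.0745 with an estimated correlation). At 9 weeks 23 had a median of 0.22, with 5 rising (camera p = 0.0105, 0.0479 with an estimated correlation). Those that rose at both ages included Peg3, at 1.91 ± 0.48 and 2.71 ± 0.22, and Igf2, at 0.88 ± 0.12 and 1.71 ± 0.28. Peg3 and Zim1, named with Igf2 after their values were seen, lie in 1 imprinted cluster with Usp29. They also rose at 30 C, at 0.44 ± 0.09 and 1.43 ± 0.27, and both passed in TrkA Th-cre libraries, with Peg3 at 0.96 ± 0.16, so their rise is not particular to the libraries labelled Prx1-cre. Without both, camera p was 0.0296 at P25 (0.13 with an estimated correlation) and 0.104 at 9 weeks (0.149), so a rise of imprinted genes beyond that cluster and the genes seen first is left open, and the label issue for Bcl6 applies to its direction.

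Other splits of the same libraries were counted for each result. The real split gave the most genes for P28 temperature (1 of 35 splits as large, 547 genes against 356 in the highest other). It did so too for TrkA (1 of 35, 317 against 14), P25 (1 of 100, 450 against 1) and adult Bcl6 (1 of 35, 1953 against 1). The highest other split for P28 temperature had 1 library with high Xist on 1 side, and each library of its other side had high Xist. That split thus lay near a split by Xist. The smallest share that 35 splits can give is 1 of 35, and shares were not adjusted over the tables. First rank therefore argues against chance without excluding it. For adult temperature, 2 of 35 splits gave as many as 542, and the highest other, the split by Xist, gave 1066. The real split did not rank first there, so chance is left open, and the samples hold a structure by sex. With the Xist indicator in the fit 2226 genes passed, and the highest of the other splits with the same Xist balance gave 1; these splits, 18 with the real one, are too few for a share under 0.05. For the differences of effects, 8 of 100 regroupings gave as many as the 166 genes of the Bcl6 effect (highest other 1471) and 7 of 100 as many as the 1051 of cooling (highest other 1866). A regrouping that keeps or mirrors the real split of 1 table carries that table's effect, as did 5 of those for Bcl6 and 1 of those for cooling. Among 100 that keep neither real split, 9 gave as many for Bcl6 (highest other 1670), so chance is not excluded, and 2 for cooling (highest other 1961). For cooling the share was under 0.05 in 1 set of draws and over it in the other, so chance is left open.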
